A study of Gallus gallus with 12 samples.

How the data were processed

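The series profiled HTC cells, a chicken macrophage cell line, after contact with 3 species of Eimeria, the intracellular protozoa that cause coccidiosis in poultry. RNA came from unstimulated cells and from cells stimulated for 4, 18 and 48 h with E. tenella, E. maxima or E. acervulina. Per the labels, each of the 12 arrays compared 2 RNA samples of one species, one labelled with Alexa555 and the other with Alexa647. The 4 arrays of a species formed a closed loop, so each of the 12 RNA samples was measured with both dyes. In no loop did an array compare the 18 h with the unstimulated RNA, so changes at 18 h carry more array error. No array was shared between species, and there was 1 RNA sample per species and time. The unstimulated RNA bears the same name in all 3 loops, and whether it was 1 RNA or 3 is not given in the sources used here. It was treated as 3.

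The authors deposited a log ratio for each spot and array, here read as log2. The base, the background correction, the normalization and which dye was the numerator are not given in the sources used here. The base was taken as 2 because it is usual for spotted arrays. Another base would rescale every change and leave the tests unfiltered by fold as they are. The table held 14718 rows. Between 12199 and 13938 rows had a value on an array, and the share of missing rows ran from 5.30% to 17.1%. Array medians lay between -0.04 and 0.12, which was taken as near 0, and the deposited values were used without further centring.

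The direction of the ratio is a likely reading only. The plan fixed before the data were examined took Alexa647 over Alexa555 as the main reading, on the basis of GEO's channel order. After the values were seen, this was changed to Alexa555 over Alexa647, because several chemokine genes, LOC395551, CCL4 and IL8L1 among them, then take the signs remembered from what the study reported. That memory could not be checked against a source. All 12 sample titles name the Alexa555 sample first, which is a weak basis. An earlier run of the same fits used the opposite sign. A list of 13 textbook induced genes, fixed in advance as a check, did not settle it: 8 of them were higher at 4 h in the reading used, with a median log2 change of 0.18. Under the other reading every sign in the text turns, and higher and lower, highest and lowest swap. Sizes, total counts and tests stay. The chemokine genes and the check list are therefore no independent evidence of a direction. The 4 arrays of a loop were taken to run the same way, which the values do not settle. After a dye effect estimated from the other loops had been removed, the sum with 4 equal signs closed best of 8 sign patterns in all 3 loops, with a median absolute deviation of 0.41, 0.36 and 0.39 against 0.55, 0.54 and 0.62 for the next best. That estimate itself assumes equal signs. Without it equal signs closed best for E. tenella and E. acervulina, but for E. maxima gave 0.69 against 0.57 with the second array turned.

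Rows were named from the platform annotation paired with the array. A single symbol was given for 9066 rows, several for 3 and none for 5649. Of the annotated rows, 8976 matched a current chicken gene record. Each of 3023 clones had 3 rows. Rows of one symbol were averaged, which merged more than one clone for 568 symbols. Rows without a symbol stood alone. The 3700 features with a value on all 12 arrays were tested, 2238 of them named.

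RNA levels relative to the loop mean were estimated by least squares, in which a constant dye effect of a feature cancels. A limma fit (version 3.58.1, in R 4.3.3) to the 12 levels had species as a block and time as a factor, with 6 residual degrees of freedom. The cultures of the 3 species served as the replicates of a time, so a mean ± SD below is over n = 3 species. The labels do not say whether the cultures were started separately, and these p-values measure only the spread between these samples. If the unstimulated RNA was 1 sample, the contrasts against it share its own deviation in all 3 replicates and their p-values are too small. Contrasts between 2 stimulated times do not use it. Species were compared with a limma F test of the stimulated minus unstimulated change, with 4 residual degrees of freedom. A single unstimulated RNA would drop out of that comparison, and its p-values would tend to be too large instead. A limma fit to the 12 arrays, with 9 species-time coefficients and a dye term, had 2 residual degrees of freedom. That fit sets RNA samples against array error and does not compare conditions. P-values were two-sided and adjusted by the Benjamini-Hochberg method, with a threshold of 0.05, and the fit to arrays also required a change of at least 2-fold. Its dye term passed the threshold for 401 features, 3 of them by at least 2-fold.

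Before the data were examined, 19 gene lists and 7 lists of markers of other cell types were fixed and were tested with camera at a preset correlation of 0.01. Members were matched by symbol or synonym, through which a few relatives entered, such as ALAS1 among the erythrocyte markers, SH2D6 and CD72L1 among the B cell markers and CD88 in antigen presentation. The named genes were fixed by rule. They are the 12 largest rises and 12 largest falls past the threshold with the same sign in all 3 species, for each time and for the mean of the times. They also include the 12 lowest p-values of the species test, and the 5 highest and 5 lowest genes per species and time past array error. Cytokines and chemokines past any test and the 4 members of each list with the largest mean change complete them. Other genes were named as members of a list or, where stated, after their values were seen.

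On simulated arrays with the spread of the real ones and 200 changed features among 3700, the fit for 4 h against unstimulated recovered 79.5% of features changed by 1 on the log2 scale, with 7 false calls, and 98.5% of those changed by 2, with 10. For the species difference the recovery was 0% at a change of 1 in 1 species and 76.0% at a change of 2. Each simulated species had its own unstimulated RNA. Alternatives covered centring, scaling, the filter on missing values, averaging, the variance model, a fold minimum, the dye term, leaving out species or arrays, and a fit to arrays instead of levels. Averaging unnamed rows by their spacing, centring the RNA levels and comparing 2 species at one time against array error were added after seeing the data. A list of 23 abundant transcripts was also drawn up after the 4 h values of some of its members had been read. The correlations between species for different times and without the unstimulated RNA were added last, when the shared name was noticed.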

Results

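The data were 12 two-channel cDNA arrays of HTC chicken macrophages, 4 for each of E. tenella, E. maxima and E. acervulina, covering unstimulated cells and 4, 18 and 48 h of stimulation. The question was which genes the macrophages change over time and how far the response differs between the parasite species. All values are log2 changes against the unstimulated RNA of the same species, in the likely direction of Alexa555 over Alexa647. The labels name no unstimulated cells kept for 4, 18 or 48 h, so stimulation and time in culture cannot be told apart. The opposite direction was the one planned, and the change was made after the values were seen. Under the other reading every sign below turns, and higher and lower, highest and lowest swap. The error of 1 array, from how far the loops failed to close, was 0.35 for E. tenella, 0.49 for E. maxima and 0.42 for E. acervulina. With the shared dye effect of each feature subtracted it was 0.29, 0.30 and 0.27.

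At 4 h the largest rise common to the 3 species was that of SPP1, which encodes the secreted phosphoprotein osteopontin, at 2.40 ± 0.09 (SD, n = 3). FABP4, a fatty acid binding protein of macrophages and adipocytes, rose by 2.28 ± 0.61. OSMR, a receptor subunit for oncostatin M, rose by 1.85 ± 0.44, LOC417536 rose by 1.85 ± 0.60 and LOC395551, which encodes a chemokine of the macrophage inflammatory protein family, by 1.71 ± 1.1. ENO1, which encodes the glycolytic enzyme enolase, fell by 1.48, with an SD of 0.49, and the death receptor gene TNFRSF10B changed by -1.32 ± 0.51 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.0024 for SPP1, 0.0096 for ENO1 and TNFRSF10B, and 0.049 for LOC395551).

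Other genes also rose at 4 h. ATP6V0D2, a subunit of the proton pump that acidifies lysosomes, rose by 1.61 ± 0.52, the lysosomal protease gene CTSD by 1.27 ± 0.61 and the endoplasmic reticulum chaperone gene HSP90B1 by 1.2 ± 0.49. DEGS1, which makes ceramide, rose by 1.30 ± 0.49, the heparan sulfate proteoglycan gene SDC1 by 1.29 ± 0.57, SYNCRIP by 1.25 ± 0.22 and TXNDC15 by 1.16 ± 0.36. Among the genes that fell were TNIP3, an inhibitor of NF-kB signalling, at -1.36 ± 0.79, ARHGAP15 at -1.30 ± 0.49, the glycogen branching enzyme gene GBE1 at -1.21 ± 0.04, TPD52 at -1.19 ± 0.61 and the mitochondrial translocator gene TSPO at -1.14 ± 0.16 (TSPO, limma with Benjamini-Hochberg adjustment, adjusted p = 0.0084). The glycolytic gene PGAM1 changed by -1.05 ± 0.38, ANXA2 by -1.05 ± 0.54, SFXN1 by -1.03 ± 0.54, NSMAF by -1.02 ± 0.32 and EXOG by -1.02 ± 0.22.

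**Figure D1:**
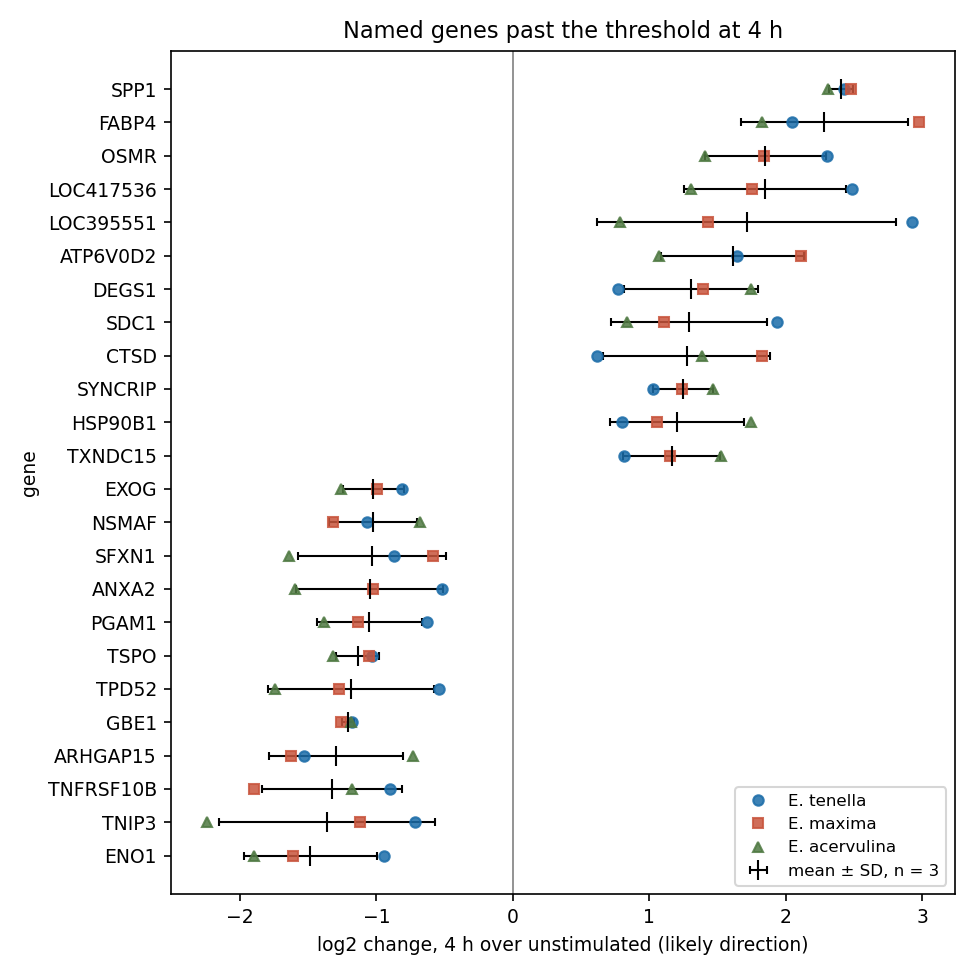
The x axis gives the log2 change at 4 h over unstimulated in the likely direction, and each row is one of the 24 genes named by rule. Points are the 3 species and bars the mean ± SD over n = 3 species; SPP1 lies between 2.31 and 2.48 in all 3.

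In all, and counting the unstimulated RNA as 3 samples, 385 of 3700 features passed at 4 h, 167 higher and 218 lower, of which 93 and 137 were named. With each array centred on its median the split was 224 higher and 180 lower. Leaving out a species left 76 features without E. tenella, 1 without E. maxima and 0 without E. acervulina.

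Of the gene groups fixed in advance, 3 passed camera at 4 h, all on the lower side. Of 55 ribosomal protein genes, 6 fell past the threshold over all features, 12 when adjusted over the list alone, and 53 had a negative change, with a median of -0.32. The medians by species were -0.23 for E. tenella, -0.14 for E. maxima and -0.60 for E. acervulina, and without E. acervulina the median was -0.19. RPL3 changed by -0.73 and RPL12 by -0.69. Of 19 glycolysis and hypoxia genes 5 fell, namely ENO1, PGAM1, NDRG1, BNIP3 and TPI1, and 6 when adjusted over the list alone. Of 30 oxidative phosphorylation genes 6 fell, including SDHD of complex II at -0.81 and ATP5L of the ATP synthase at -0.61, and 10 when adjusted over the list alone. Camera with Benjamini-Hochberg adjustment gave adjusted p = 5.0e-07 for the ribosomal list and 0.0018 for each of the other 2. With an estimated correlation none held, at adjusted p = 0.65 for each.

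The lists below held members past the threshold in both directions at 4 h and did not pass camera. Of 25 lysosomal genes, CTSD, CTSK and CTSC rose, CTSK by 0.93 and CTSC by 0.92, while the cholesterol transport gene NPC2 fell, at -0.52. Of 23 heat shock and folding genes, HSP90B1, HSPA5 and CCT4 rose, HSPA5 by 0.84, while PPIA and HSPE1 fell. Of 25 Toll-like receptor and NF-kB genes, the kinase gene TBK1 rose by 0.81, and LY96, the lipopolysaccharide co-receptor, and TLR2A fell, at -0.96 and -0.81. Of 30 macrophage genes SPP1, FABP4 and CEBPB rose, while LYZ, which encodes lysozyme, and ANXA2 fell, LYZ at -0.93. The camera adjusted p after Benjamini-Hochberg adjustment was 0.25 for the lysosomal list, 0.36 for heat shock and folding, 0.88 for Toll-like receptors and NF-kB and 0.28 for the macrophage list.

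At 18 h FABP4 remained high, at 2.47 ± 0.33, and HIF1A, the oxygen-regulated transcription factor subunit, rose by 1.07 ± 0.11. The receptor phosphatase gene PTPRJ rose by 1.30 ± 0.16, the intramembrane protease gene SPPL2A by 1.18 ± 0.11, the metalloproteinase inhibitor gene TIMP4 by 1.11 ± 0.60 and LARP4B by 1.02 ± 0.41. TNFRSF10B fell, at -1.07 ± 0.17, as did PGAM1 at -0.85 ± 0.11, SPTY2D1 at -0.84 ± 0.11, the ubiquinone biosynthesis gene COQ5 at -0.79 ± 0.05, TSPO at -0.70 ± 0.07 and the MAP kinase phosphatase gene DUSP6 at -0.57 ± 0.04 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.036 for HIF1A, PTPRJ and TNFRSF10B). TFPI, PPP2R5C, UGGT1, N4BP2, PUM2 and SYNCRIP rose by between 0.83 and 0.98. ATP5L, CD300LG, SDHD, ADH4, PTMA and NSA2 fell, with changes between -0.71 and -0.60.

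At this time 60 features passed, 42 higher and 18 lower, of which 19 and 12 were named. Changes at 18 h carry more array error than those at 4 and 48 h, so this count does not rank the times. No ribosomal protein gene passed singly at 18 h, yet 53 of 55 had a negative change and the median was -0.26, or -0.16 without E. acervulina. Of 30 oxidative phosphorylation genes SDHD and ATP5L fell, 11 fell when adjusted over the list alone, and the median was -0.29. Camera with Benjamini-Hochberg adjustment gave adjusted p = 6.8e-08 for the ribosomal list and 1.0e-04 for oxidative phosphorylation, which became adjusted p = 0.80 and 0.64 with an estimated correlation. The count of 60 became 5 when features with 3 of 4 arrays per loop were admitted and 1, 0 and 0 without E. tenella, E. maxima and E. acervulina.

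**Figure D2:**
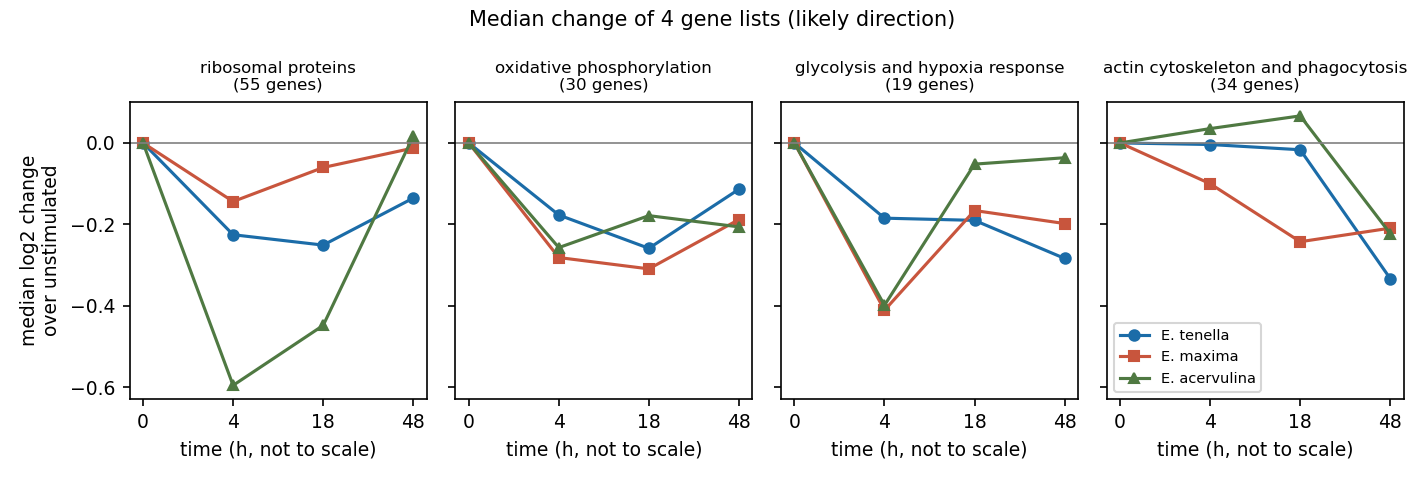
Each panel shows the median log2 change over unstimulated of 1 gene list against time in h, with a line per species and 1 RNA sample per point. Ribosomal protein genes lie at -0.60 at 4 h for E. acervulina, the lowest point, and return to between -0.14 and 0.02 at 48 h.

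At 48 h FABP4 was higher by 2.31 ± 1.46 and HIF1A by 1.23 ± 0.40. The Polycomb gene PCGF5 rose by 1.23 ± 0.37, MPST, which makes hydrogen sulfide, by 1.1 ± 0.27, and LARP4B by 1.04 ± 0.45. The pattern recognition receptor gene TLR2A fell, at -1.35 ± 0.34, as did PCNA, the DNA polymerase clamp, at -1.13 ± 0.37, and ALOX5AP, needed for leukotriene synthesis, at -1.13 ± 0.55. DBI changed by -1.07 ± 0.44, the glutathione transferase gene GSTA3 by -1.0 ± 0.20 and CYBB, the catalytic subunit of the phagocyte oxidase, by -0.89 ± 0.61 (limma with Benjamini-Hochberg adjustment, adjusted p = 0.025 for TLR2A, 0.026 for PCNA and 0.039 for CYBB).

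YPEL5, TMEM106B, UGGT1, TFPI, CROT, RICTOR and RB1CC1 rose at 48 h by between 0.85 and 0.93. CKLF, TNFRSF10B, LOC426820, PDCD4, CCND3 and LAPTM5 fell, with changes between -0.98 and -0.84. Of 34 actin cytoskeleton genes ARPC4 of the Arp2/3 complex and the myosin light chain gene MYL12A fell, at -0.75 and -0.42, and 31 had a negative change. Adjusted over the list alone, 9 fell and 1 rose. This list passed camera with Benjamini-Hochberg adjustment at adjusted p = 6.0e-04, and adjusted p = 0.96 with an estimated correlation. Of 20 oxidative and nitrosative defence genes CYBB, GSTA3, PRDX1 and GSTO2 fell and none rose over all features, while 6 fell and 1 rose when adjusted over the list alone (camera with Benjamini-Hochberg adjustment, adjusted p = 0.90). PCNA and CCND3 were the 2 of 13 cell cycle genes that fell, and CASP8, PDCD4 and TNFRSF10B the 3 of 13 apoptosis genes.

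The 48 h count was 133 features, 64 higher and 69 lower, of which 37 and 45 were named. With arrays centred the split was 75 higher and 48 lower. The count was 37 with features of 3 of 4 arrays per loop admitted, and 1, 0 and 2 without E. tenella, E. maxima and E. acervulina.

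Over the mean of the 3 times FABP4 rose by 2.36 (SE 0.39), ATP6V0D2 by 1.52 (SE 0.29), K123 by 1.21 (SE 0.32), LARP4B by 1.02 (SE 0.15) and the drug transporter gene ABCC4 by 0.99 (SE 0.21). TNIP3 fell, at -1.22 (SE 0.28), TNFRSF10B at -1.11 (SE 0.15), ENO1 at -1.02 (SE 0.17), DBI at -0.92 (SE 0.14) and TLR2A at -0.91 (SE 0.17), by limma with Benjamini-Hochberg adjustment, adjusted p = 0.011 for TNFRSF10B and 0.016 for FABP4. PCGF5, GOLGA3, SPP1, UGGT1, SLC35F5, SYNCRIP and RASGRP1 rose by between 0.83 and 0.99, and GBE1, PGAM1, ALOX5AP, ARHGAP15, LAMP5, TSPO and PDCD4 fell, with changes between -0.85 and -0.76. In this contrast 387 features passed, 154 higher and 233 lower, and 195 higher and 176 lower with arrays centred. Any-time testing found 334. Without E. tenella, E. maxima and E. acervulina the mean left 4, 0 and 0 features and any time 0, 1 and 0, while scaling left 166 for the mean and the wider filter on missing values 1 for any time. Ribosomal protein genes, 5 of 55 past the threshold and 0 adjusted over the list alone, and oxidative phosphorylation genes, 9 of 30 and 13 adjusted over the list alone, were the lists that passed camera, at adjusted p = 3.2e-05 and 6.3e-04 after Benjamini-Hochberg adjustment. With an estimated correlation both had adjusted p = 0.83.

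SPP1 was the one feature that changed between 4 and 18 h, by -1.83, with adjusted p = 0.026 (limma with Benjamini-Hochberg adjustment). Its changes were 2.42, 2.48 and 2.31 at 4 h for E. tenella, E. maxima and E. acervulina, and its common change was 0.58 at 18 h and -0.22 at 48 h, neither past the threshold. The count of 1 became 24 with arrays scaled to one spread, and the call on SPP1 was lost when any species was left out, at adjusted p from 0.053 to 0.35. From 18 to 48 h limma called 0 features, with 501 at an unadjusted p under 0.05 and a lowest adjusted p of 0.25.

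**Figure D3:**
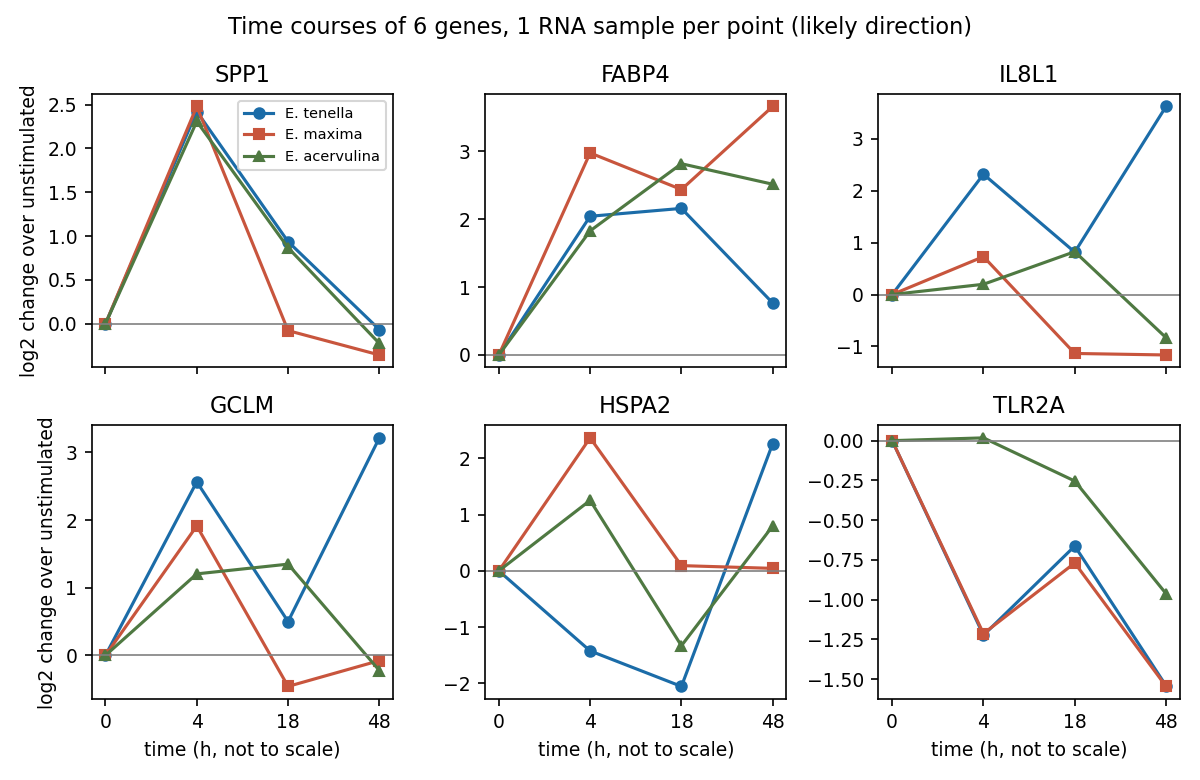
Each panel plots the log2 change over unstimulated of 1 gene against time in h, with a line per species and 1 RNA sample per point, so the points have no replicate error. SPP1 peaks at 4 h in all 3 species, while IL8L1 reaches 3.62 at 48 h with E. tenella and lies at -1.16 and -0.83 with the other species.

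No feature showed a difference between species in the mean stimulated change by the limma F test. There were 113 features at an unadjusted p under 0.05, where chance gives 185, and the lowest adjusted p was 0.9997. If the unstimulated RNA was 1 sample, its deviation drops out of a difference between species, and these p-values tend to be too large. Whether that gave the low count was not tested. The genes with the lowest p-values were RIN2, a Rab5 exchange factor, with mean changes of -0.29, 0.55 and 1.24 for E. tenella, E. maxima and E. acervulina, RC3H1 with -0.19, 1.61 and 0.49, and CCNC with -0.30, -0.10 and 1.17. GDAP2, ZMYM4, DCUN1D3, YPEL5, GLYCTK, RGS1, CYBB, SPCS3 and CTBS came next. The 95% interval of a difference between 2 species had a median width of 0.67 to either side, and in simulated data no difference of 1 on the log2 scale was recovered, so the absence of calls does not show that the species act alike.

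Across features, which are not independent replicates, the responses to the 3 species were positively correlated at each time. Pearson r between 2 species lay between 0.45 and 0.53 at 4 h, 0.37 and 0.50 at 18 h, and 0.22 and 0.51 at 48 h. The unstimulated RNA bears one name in all 3 loops, and a single RNA used in each would by itself make the species look alike. Between different times of 2 species r averaged 0.31 (0.10 to 0.49), which holds any general response together with any shared control. Changes from one stimulated time to another, which leave the control out, had a mean r of 0.26 between species (-0.02 to 0.45). They were 0.40, 0.30 and 0.32 for 18 h against 4 h, -0.02, 0.33 and 0.07 for 48 h against 18 h, and 0.19, 0.30 and 0.45 for 48 h against 4 h, for E. tenella with E. maxima, E. tenella with E. acervulina and E. maxima with E. acervulina. No spread was estimated for these. Spearman rho at 48 h was 0.35 for E. tenella with E. maxima, 0.27 for E. tenella with E. acervulina and 0.55 for E. maxima with E. acervulina. Times of one species share their unstimulated RNA, which gave r of about 0.49 to 0.50 in simulated unchanged groups. The simulation drew RNA levels independently and left out the array errors that the levels of a loop share. Such errors raise r for 4 with 18 h and 18 with 48 h, and lower it for 4 with 48 h, which shared no array. The simulated values are therefore no exact baseline, and no conclusion is drawn from them. Observed r between 4 and 18 h was 0.62, 0.66 and 0.71 for E. tenella, E. maxima and E. acervulina, with covariances of 0.11, 0.16 and 0.15 against a simulated 0.05. Between 4 and 48 h r was 0.37, 0.56 and 0.28, with covariances of 0.06, 0.15 and 0.05, the last equal to the simulated 0.05. Between 18 and 48 h r was 0.36, 0.81 and 0.49, with covariances of 0.07, 0.19 and 0.08 against a simulated 0.05.

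The following single-species values rest on 1 RNA sample each, and limma set them against array error only. In E. tenella cultures at 4 h the highest genes past array error were LOC395551, LOC417536 and the chemokine gene IL8L1, at 2.92, 2.48 and 2.31, with SPP1 at 2.42 and GCLM, the glutathione synthesis subunit, at 2.56. ARHGAP15, HSPA2, LY96, NDRG1 and TLR2A were lowest, at -1.53 to -1.22. At 18 h SLA reached 3.71, EIF5B 2.27, K123 1.91 and the prostaglandin synthase gene PTGS2 1.74, and LOC395551 was at 2.74, while HSPA2, FOS and HSPA8 lay at -2.05, -1.79 and -1.46. At 48 h IL8L1 and GCLM were highest, at 3.62 and 3.22, followed by K123, CSTA and HSPA2 at 2.54, 2.33 and 2.26. TXNDC17, TLR2A, GBE1, ARHGAP15 and FAS lay between -1.57 and -1.39.

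In E. maxima cultures at 4 h FABP4 and SPP1 were followed by HMOX1, the heme-degrading enzyme gene, HSPA2 and COX4I1, at 2.39, 2.37 and 2.35, and TNFRSF10B, ARHGAP15, ENO1, FAS and FAM72A were lowest, at -1.90 to -1.43. At 48 h FABP4 stood at 3.66, XBP1, a transcription factor of the unfolded protein response, at 3.43, FRMD4B at 2.64, SESN1 at 2.43 and SLC35F5 at 1.85, and AVD, ALOX5AP, DBI, TLR2A and PCNA at -1.66 to -1.45. In E. acervulina cultures at 4 h SPP1, the complement gene C1QC and RNASE6 were highest, at 2.31, 2.24 and 2.23, then FABP4 and HACD2, and TNIP3, ENO1, TPD52, SFXN1 and RGS1 lowest, at -2.24 to -1.63. At 18 h FABP4, MMP1 and IL18 stood at 2.82, 2.13 and 1.83, LOC417536 and OSMR at 1.62 and 1.5, and PGM2, TARP, STK4, HSPA2 and SAT1 between -1.43 and -1.22.

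Past array error and at least 2-fold were 34, 21 and 91 features at 4, 18 and 48 h with E. tenella, 137, 0 and 160 with E. maxima, and 146, 29 and 0 with E. acervulina. The 2 counts of 0 (limma, with 1069 and 995 features at an unadjusted p under 0.05) stood beside 141 and 58 features at least 2-fold changed by value alone. With 2 residual degrees of freedom, leaving out 1 array of a loop brought every such count for its species to 0 or 1, so the counts do not rank the species or times.

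Cytokine and chemokine genes did not pass as groups. TGFB3 was the 1 of 8 cytokine genes and LOC395551 the 1 of 10 chemokine genes past the threshold at 4 h, with 1 and 0 adjusted over the list alone, and neither list passed camera at any time, the lowest adjusted p after Benjamini-Hochberg adjustment being 0.22. TGFB3 stood at 0.69, 0.40 and 0.96 at 4 h with E. tenella, E. maxima and E. acervulina. IL8L1, an interleukin 8-like chemokine, stood at 2.31, 0.82 and 3.62 at 4, 18 and 48 h with E. tenella, at 0.73, -1.13 and -1.16 with E. maxima and at 0.20, 0.82 and -0.83 with E. acervulina. LOC395551 was at 1.43, 0.12 and -0.23 with E. maxima and at 0.79, 1.48 and -0.79 with E. acervulina. CCL5 reached 1.42 at 48 h with E. tenella and 1.03 with E. maxima, and lay at -0.37 with E. acervulina. CCL20 was 1.68 at 48 h with E. tenella, but was not highest with E. tenella at every time. Its E. tenella minus E. maxima differences were -0.61, 0.08 and 1.64 at 4, 18 and 48 h. Against E. acervulina they were -0.79, -1.76 and 1.055, and none of these differences passed array error. CCL26 and CCLL4 stayed between -0.48 and 0.97 in all 9 RNA samples.

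Few markers of other cell types were measured. The T and natural killer cell list had 3 measured genes, with median changes of 0.13, -0.25 and -0.17 at 4, 18 and 48 h. In single RNA samples that list's median ran from -0.63 for E. maxima at 48 h to 0.51 for E. acervulina at 18 h. The B cell list had 4, with medians of -0.11, -0.11 and -0.26, the erythrocyte list 4, with -0.13, -0.14 and -0.12, the thrombocyte list 2, with -0.08, 0.04 and -0.03, and the heterophil list 3, with 0.20, 0.03 and -0.04. The fibroblast list was FN1 alone, at 0.38, 0.14 and -0.05, and the intestinal epithelium list CDH1 alone, at 0.31, 0.28 and 0.00. None passed camera, with Benjamini-Hochberg adjusted p of 0.36 or more. Past the threshold in these lists were CA2, higher at 4 h by 0.42 and at 18 h by 0.61, and ALAS1, lower at 4 h, at -0.63. The interferon response list had 0 of 21 genes past the threshold at any time. The antigen presentation list had 2 of 15 lower at 4 h, the immediate early and MAP kinase list 2 of 15, and the cytokine receptor list 1 of 20 higher, IL1RAP, while FABP4 rose and ALOX5AP fell among 13 lipid genes.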

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

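The comparisons of 2 species at one time, the 2 tests on IL8L1, the sign test of the ratio's direction and the list of abundant transcripts, some of whose 4 h values had been read, were chosen only after values were seen. The comparisons of 2 species set single RNA samples against array error in the limma fit, and no difference between species passed the test over times.

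SPP1 differed between 18 h and 4 h by -1.83, the one feature to do so.

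Of the 9 comparisons of 2 species at one time 6 gave 0 features past array error, with 416 to 717 at an unadjusted p under 0.05, among them all 3 at 18 h. Changes at 18 h carry more array error than those at 4 and 48 h. By value alone 170, 147 and 192 features differed at least 2-fold at 18 h, against 116, 150 and 143 at 4 h. These are for E. tenella with E. maxima, E. tenella with E. acervulina and E. maxima with E. acervulina. The counts of 0 therefore do not show that the species differ less at 18 h. Between E. tenella and E. maxima, 1 feature differed past array error by at least 2-fold at 4 h, HSPA2, an HSP70 family gene, by -3.79, and this call was lost with scaling and with any 1 array left out, leaving 0. A fit with an array left out has fewer residual degrees of freedom than the 2 of the full fit. Calls lost there can be lost for that alone. At 48 h 85 features differed so between these 2 species, among them unnamed rows that stood alone, so spots of 1 clone may count more than once. That count became 1 without the dye term, 1 with scaling and 0 with any 1 array left out. Of the 53 named ones 27 were higher with E. tenella and 26 lower, and those below were picked from them after the values were seen. E. tenella was higher for IL8L1 by 4.78, GCLM by 3.29, AVD, which encodes avidin, by 2.86, HSPA2 by 2.22, KLF2 by 2.20, HSPA8 by 2.10, PLEKHA1 by 2.08, HMOX1 by 1.75, TXNRD1 by 1.72 and HSP90AA1 by 1.51. The E. tenella minus E. maxima difference was -2.90 for FABP4, -2.45 for SLA, -1.64 for NCF4 and -1.04 for IL18. Between E. tenella and E. acervulina 10 features differed at 48 h, which became 1 without the dye term and 0 with any 1 array left out, among them IL8L1 by 4.45, GCLM by 3.44, CSTA by 2.37, KLF2 by 2.23, AVD by 2.15 and K123 by 2.02.

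IL8L1 after E. tenella at 48 h stood far from the other species. A fault of the spots of 1 clone is argued against, since the 2 clones of this gene, with 3 spots each, gave differences from E. maxima of 4.62 and 5.06, the smaller with a spot SE of 0.12. A fault of 1 array is argued against as well, since with each of the 8 arrays left out in turn the smallest difference was 4.76, with an SE of 0.16. A difference between the parasite species and one between single cultures both stay open, because each species and time had 1 RNA sample.

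The ribosomal protein genes had a median at 4 h that was -0.30 relative to all named genes. For the mean of the 3 species, uneven ratios of single arrays are argued against, as long as what the 3 loops share is a dye effect, which cancels in the RNA levels. The list's sums round the loops were -0.54, -0.62 and -0.36, and the largest departure from their mean was 0.15, smaller than the shift by more than the SE of 0.04. That SE comes from resampling the genes and does not measure the spread between arrays or RNA samples. For E. maxima the departure was -0.12 beside a median change of -0.14, so for that species alone unevenness stays open. A shift of abundant transcripts of any kind may account for part of it, since the median of 23 such transcripts outside translation was -0.17, past the bound of 0.5 times the ribosomal shift, -0.15, but by far less than its SE of 0.09. An effect of the stimulation on translation genes and one of time in culture both stay open and cannot be told apart.

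The direction of the ratio was not settled by these values. Of the 13 textbook induced genes 8 were higher at 4 h in the reading used, and an exact two-sided sign test gave p = 0.58. LOC395551, CCL4 and IL8L1, by which the reading was chosen, are among these 8. The count is therefore no lean toward that reading. The reading as Alexa555 over Alexa647 is therefore only likely, and it rests on the titles' order and on what is remembered of the study. GEO's channel order, on which the plan rested, goes against it.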

How the results depend on the processing

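The comparisons between 2 species at one time, the unnamed rows averaged by spacing and the centring of RNA levels were chosen after seeing the data. Signs were followed for named genes past the threshold in the common response, past array error in 1 species, or picked from the comparisons of 2 species. None of these signs reversed in the alternatives that followed them, but for most of these genes only centring and scaling could have reversed a sign. The variance model, the dye term, the wider filter, averaging unnamed rows and the fit to arrays leave these estimates unchanged. Most genes of the common response were chosen for the same sign in all 3 species, so leaving out a species could not turn it. The runs with separate rows and with 1 array left out did not follow signs. Many calls on these genes were lost: 82 of 97 without E. tenella, 96 of 97 without E. maxima, 96 of 97 without E. acervulina and 58 of 97 with the wider filter. With scaling 69 were lost and 117 kept, and without the dye term 59 were lost and 30 kept. The cause of a move was not tested unless stated. In the order 4 h, 18 h, 48 h, mean of the times and any time, the counts of the common response were 385, 60, 133, 387 and 334. With arrays scaled to one spread, 4 h gave 254, 18 h 33 and the mean 166. Admitting features with 3 of 4 arrays per loop raised the features tested to 6825 and gave 5 at 18 h, 37 at 48 h, 208 for the mean and 1 for any time. In a loop with an array missing the dye effect of a feature does not cancel. Features with all 12 values kept their estimates, so their calls were lost only through the shared variance estimate and the adjustment. Rows tested separately gave 38 at 18 h. A 2-fold minimum left 60, 11, 21, 12 and 61, and a fit to the 12 arrays gave 742 at 4 h, 485 at 48 h, 673 for the mean and 816 for any time. That fit treats arrays as independent although each RNA sample was on 2 of them, so its larger counts are no stronger evidence. For 18 h against 4 h the count of 1 became 3 with centring, 24 with scaling, 0 with the wider filter, 4 with separate rows, 50 in the fit to arrays and 0 without any species. Without 1 species the counts ran from 0 to 76 at 4 h (76 without E. tenella), 0 to 1 at 18 h, 0 to 2 at 48 h, 0 to 4 for the mean and 0 to 1 for any time. These fits have fewer samples. On simulated data the 2 species left without E. tenella recovered 60.5% of features changed by 1 at 4 h, alike in all species. Of the 385 real calls at 4 h only 60 reached a change of 1. The simulation therefore does not tell how many of them a fit to 2 species should keep. At 4 h, 347 of the 404 features called with centring were called without it, as were 249 of 254 with scaling and 223 of 379 with the wider filter. The species difference stayed at 0 in all alternatives run.

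Against array error, the counts at 4, 18 and 48 h were 34, 21 and 91 for E. tenella, 137, 0 and 160 for E. maxima, and 146, 29 and 0 for E. acervulina. Without the dye term they were 7, 0 and 9 for E. tenella, 60 at 4 h and 20 at 48 h for E. maxima, and 81 at 4 h and 0 at 18 h for E. acervulina. Scaling gave 72 at 4 h and 5 at 18 h for E. tenella, 3 at 4 h and 75 at 48 h for E. maxima, and 94 at 4 h and 0 at 18 h for E. acervulina. Without a 2-fold minimum there were 370 at 48 h for E. tenella, 678 at 4 h and 928 at 48 h for E. maxima, and 767 at 4 h for E. acervulina, and robust eBayes gave 13 at 18 h for E. tenella. With any 1 array of the loop left out the counts ran from 0 to 0 for E. tenella and E. acervulina, and from 0 to 1 at 4 h and 0 to 0 at 48 h for E. maxima. The 48 h counts of 85 and 10 between E. tenella and the other species both became 1 without the dye term, the 85 became 1 and the single feature at 4 h became 0 with scaling, and each ran from 0 to 0 with an array left out. The lists past the threshold, 3 at 4 h, 2 at 18 h, 1 at 48 h and 2 for the mean, became 0 at each with an estimated correlation. Without a species they ran from 3 to 5 at 4 h, 2 to 2 at 18 h, 1 to 2 at 48 h and 2 to 2 for the mean. The array error became 0.30 for E. maxima and 0.27 for E. acervulina with the dye effect subtracted.

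Other assignments of the times within species tested whether chance can be excluded. For the mean of the times, of 64 choices of the control RNA only the real 1 of 64 gave as many as 387 features, and the highest other gave 239. For any time only the real 1 of 100 drawn assignments gave as many as 334, the highest other giving 3. Both exclude chance only if the unstimulated RNA was 3 separate samples. If it was 1, the real assignment alone lines up that sample's own deviation in all 3 loops, and these shares do not exclude chance. For the species difference the real count was 0, which all 64 of 64 reach whatever the data, with a highest other of 3, so this says nothing about chance. For single times only 4 assignments exist, too few for a share under 0.05. The real counts were 385, 60 and 133 at 4, 18 and 48 h and 1 for 18 h against 4 h, each reached by 1 of 4, with a highest other of 0, and the count of 0 for 48 h against 18 h is reached by 4 of 4 whatever the data, with a highest other of 0.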

Other observations

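The heat shock and redox genes named here were chosen after their values were seen, and each value is 1 RNA sample. HSPA2 stood at -1.42, -2.05 and 2.26 at 4, 18 and 48 h with E. tenella, at 2.37, 0.09 and 0.04 with E. maxima and at 1.25, -1.33 and 0.80 with E. acervulina. HSPA8 stood at -0.18, -1.46 and 1.5 with E. tenella, and HSP90AA1 at -0.87, -0.91 and 1.28, while at 4 h both were higher with E. maxima, at 0.81 and 0.84, and with E. acervulina, at 1.06 and 1.16. In the reading used, the redox genes HMOX1 and TXNRD1 had their highest value at 48 h with E. tenella, at 1.0 and 1.41, and at 4 h with E. maxima, at 2.39 and 1.31, and E. acervulina, at 1.28 and 0.85. Under the other reading these are their lowest values. GCLM was high at both 4 h and 48 h with E. tenella, at 2.56 and 3.22. It was also high at 4 h with E. maxima, at 1.91, and at 4 and 18 h with E. acervulina, at 1.2 and 1.35. At 48 h it lay at -0.08 and -0.22 with E. maxima and E. acervulina.

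COX4I1, a subunit of cytochrome oxidase, lay apart from the median of the oxidative phosphorylation list in 2 RNA samples. It stood at 2.35 at 4 h with E. maxima and -2.11 at 18 h with E. acervulina, where the list medians were -0.28 and -0.18. The value of -2.11 was not past array error (limma with Benjamini-Hochberg adjustment, adjusted p = 0.069). The spread of the other members was not examined. XBP1 reached 3.43 at 48 h with E. maxima and lay at -0.04 and 0.58 with E. tenella and E. acervulina.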
